A study of Mus musculus with 2 samples.

How the data were processed

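RNA sequencing of day 7 pancreatic spheres was compared between shScramble and shDpy30, with 1 library of each described. Per the labels, infected bud cells were selected with puromycin at 1 ug/mL, more than 4 sphere differentiations were pooled per library, more than 500 ng of RNA was used, and TruSeq kits were sequenced on HiSeq or NextSeq instruments. Per the submitters' processing notes, reads were assigned with Salmon, mm10 was the genome build, and DESeq2 was used for differential expression; versions are not given in the sources used here. An shWdr5 arm named in the series' design was not analysed here.

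The data consisted of 1 table of the authors' comparison. Its mean level is a never-negative signal, deposited by the authors as DESeq2's mean of normalized counts over the libraries of their fit. Which libraries and how many entered that fit is not given in the sources used here. The log2 fold change and its standard error on the log2 scale were deposited by the authors without a stated direction. The statistic is a score deposited by the authors, and it equalled the fold change over its standard error to within rounding. The p-value and the adjusted p-value were deposited by the authors; the p-value was checked to be the two-sided normal p of the score, and the adjusted one to be Benjamini-Hochberg over all 18457 rows to within 8.08e-05. Fold changes, errors and p-values of single genes in the text are those of the authors' deposited table, except where another adjustment or a trend correction is named. List medians and means, relative standard errors, trend corrections and bootstrap errors were computed here from that table. No sample number was added. No level per library is used, so library depth is unknown and no interval that needs counts is given. Values per library would have been required for the per-library Dpy30 level that was planned, and the deposited fold change stands in its place.

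Genes were called changed at the authors' adjusted p under 0.05. With 1 library per group analysed here, and the libraries of the authors' fit not given, the p-values are not read as a test across biological replicates. Gene lists were fixed before the data were examined (30 lists, of which 29 had at least 5 members at a mean normalized count of at least 20). For each list the median log2 fold change was set against 10000 random lists of the same size, drawn from the same 20 bins of mean normalized count. The number of random lists at or below the median is given as a description, not a p. For counts adjusted over the list alone, the authors' unadjusted p-values were adjusted by Benjamini-Hochberg within the list. No gene-wise test of per-library values was run.

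Genes were named by a rule fixed before the data were examined. It takes Dpy30, then up to 15 genes with the largest increase and 15 with the largest decrease among those past the threshold at a mean normalized count of at least 100, leaving out predicted, Y-linked and unnamed genes and Xist. From each list it takes the 4 members with the largest change, and it always includes 14 genes of the complex and of pancreatic lineages. Not all genes that the rule takes are printed in the Results. Left out there are, among others, the hormone list genes Tph1 (-3.27 ± 1.70) and Ucn3 (-2.59 ± 1.40). The acinar gene Klk1 (-2.69 ± 1.37) and the S phase gene Pola1 (-0.51 ± 0.52) are also left out. Other genes in the text (Irf7, Ins1, Sst, Ghrl, Ctrb1, Col3a1, Fn1, Egfl7 and those in the closing section) were chosen after their values were seen.

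Transcript length and GC content were taken from the longest GENCODE vM21 transcript of each gene, matched by symbol or through the Entrez identifier in the RefSeq table, for 18226 of 18457 genes (98.7%). The trend was removed by subtracting the median of each cell of 20 length bins and 10 GC bins. Gene positions are from the same annotation of GRCm38, the assembly that mm10 names. A further 9 lists (Wnt ligands, elastic fibre, smooth muscle, primary cilium, nuclear long non-coding RNA, MHC class I, imprinted, snoRNA and microRNA genes) were examined after the values had been seen. Alternatives covered the threshold, the floor on mean level, the adjustment, the matching and summary of list values, and the centre of the fold changes. For list means, fold changes beyond 10 on the log2 scale were set to 10 of the same sign.

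The calls, the list medians and the length and GC correction were tested on simulated data; the span correction, the robust-spread scaling and the relative standard errors were not. With unshifted lists of 20 and 40 genes, 1 of 25 simulated medians fell outside the central 95% of random lists at each size, and 0 of 25 for lists of 10. With a planted shift of 0.4 on the log2 scale, 18 of 25 lists of 10 genes, 22 of 25 of 20 and 25 of 25 of 40 did. With a planted shift of 0.2, near the size of many list medians in the text, 6 of 25, 14 of 25 and 21 of 25 did, so a list inside the range is not shown to be unshifted. The noise of these simulated lists was independent between genes and narrower than the deposited standard errors. Genes of a real list are regulated together, so these counts need not hold for the real lists. A planted GC trend of 0.98 between outer deciles was 0 after correction, while the median of a shifted list went from -0.75 to -0.78. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.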

Results

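Gene expression was measured by RNA sequencing in mouse pancreatic spheres, the clusters that embryonic pancreas cells form when cultured in Matrigel, a basement membrane gel. Cells of the dorsal pancreatic bud were taken from CD-1 embryos at embryonic day 13.5 and infected with lentivirus carrying a short hairpin RNA. The hairpin either had a scrambled sequence (shScramble) or was directed against Dpy30 (shDpy30). The spheres received retinoic acid at 0.33 uM for 3 days, differentiation medium on days 4 and 6, and were collected on day 7. There was 1 library per group, each made from a pool of more than 4 sphere differentiations, so with the libraries described here the difference between the groups has no replicate check. Which libraries entered the authors' fit, and so lie behind its fold changes and errors, is not given in the sources used here. The authors' deposited table compares the groups gene by gene and holds 18457 genes with a mean normalized count from 1.56 to 559857 (median 696). It gives no values per library, so the depth of each library is unknown. At a mean normalized count of at least 20, which 15396 genes reached, the median standard error (SE) of the log2 fold change in the authors' deposited table was 0.51. For genes at 100 or more it was 0.49, which puts 1.96 standard errors at a log2 fold change of 0.96. All fold changes are shDpy30 over shScramble. The table's header does not state the direction, which was read from Dpy30 itself. The p-values come from the authors' fit, and since its libraries are not given in the sources used here, what spread they measure is not known.

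The question of the comparison was what loss of Dpy30 does to pancreatic progenitors as they differentiate. Dpy30 is a core subunit of the Trithorax group (TrxG) or COMPASS complexes, which methylate histone H3 at lysine K4. The Dpy30 gene (Entrez Gene 66310, chromosome 17, 74299474 to 74323944 in mm10, minus strand) had a log2 fold change of -1.98 ± 0.48 (SE) in the authors' deposited table, at a mean normalized count of 1221. That is a 3.95-fold lower level, with an unadjusted p of 3.72e-05 and an adjusted p of 0.138 in the authors' deposited table. With the statistics divided by their robust spread, an alternative chosen after the data were seen, its adjusted p was 1.61e-05. That spread was below 1 in every bin of mean level (0.50 to 0.97), so the scaling lowers every unadjusted p by construction. It takes the authors' errors to be too wide, which was not tested. Because the direction was read from this gene, its sign is not an independent check of the labels. The transcripts of the other shared core subunits lay within 1 SE of no change in the authors' deposited table: Wdr5 at 0.04 ± 0.44, Ash2l at -0.15 ± 0.43 and Rbbp5 at -0.06 ± 0.43. The catalytic subunit genes Kmt2c (-0.80 ± 0.48) and Kmt2d (-0.67 ± 0.48) and the complex member Bod1l (-0.94 ± 0.53) were the next largest differences of the list in the authors' deposited table. Of the 22 TrxG and COMPASS genes, 11 lay above 0 and 11 below, with a median of 0.01, and 4456 of 10000 random lists of like abundance were at or below it. The mean of this list was -0.16, below the central 95% of random lists, but it includes the targeted gene Dpy30 at -1.98. Without Dpy30 the median was 0.04, inside that range, and the mean without it was not computed. None passed over all genes, and Dpy30 alone passed when adjusted over the list alone. The 21 Polycomb genes, which encode the opposing repressive complexes, had a median of 0.06, and 6341 of 10000 random lists were at or below it. Their largest differences in the authors' deposited table were Cbx6 at 0.76 ± 0.43 and Mtf2 at -0.64 ± 0.47. The Hox genes, known targets of both systems, had a median of 0.12 over 20 members, inside the central 95% of random lists, between Hoxb8 at -1.19 ± 0.78 and Hoxb2 at 0.95 ± 0.66 in the authors' deposited table.

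Over all genes, 2 rose and 0 fell at an adjusted p under 0.05 in the authors' deposited table. Spon2, which encodes the secreted matrix protein spondin 2 (Entrez Gene 100689, chromosome 5, 33198184 to 33218455, minus strand), rose by a log2 fold change of 2.12 ± 0.45, or 4.34-fold, with an adjusted p of 0.0488 in the authors' deposited table. Pcsk6, a proprotein convertase that processes TGF-beta family ligands (Entrez Gene 18553, chromosome 7, 65861734 to 66050386, plus strand), rose by 2.13 ± 0.47, or 4.39-fold, with an adjusted p of 0.0488 in the authors' deposited table. Both values lie near the threshold, and at 0.01 no gene passed. At an unadjusted p under 0.05, 182 genes were higher and 322 lower in the authors' deposited table, which together is 2.73% of all rows, against 5% expected without any effect. The deposited statistics were narrower than a standard normal (SD 0.85 over genes at or above the floor). In data simulated with these standard errors, 4 of 200 genes changed by 2-fold were recovered, 93 of 200 changed by 4-fold and 138 of 200 changed by 8-fold. False calls numbered 0, 5 and 7. The simulated noise was drawn at the full standard error, while the deposited statistics were narrower, and all 200 planted genes shared the same fold. These counts therefore do not give the share recoverable from the deposited table, where Dpy30, 3.95-fold lower, did not pass.

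**Figure D1:**
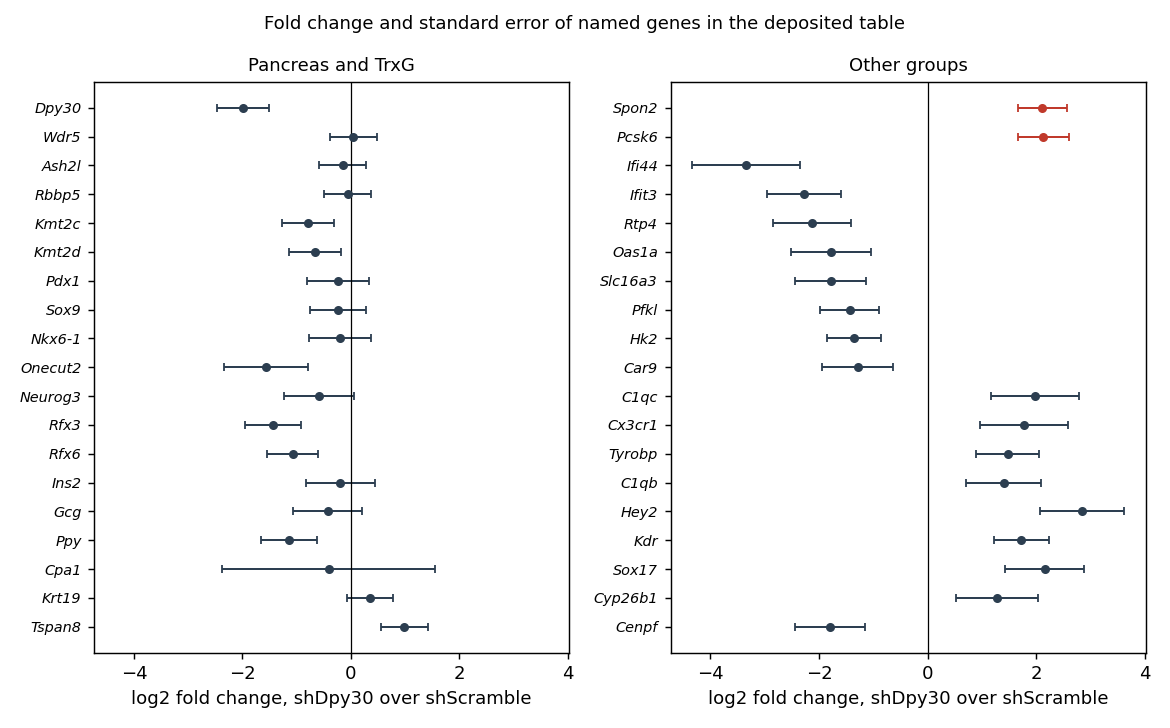
Log2 fold change (x axis, shDpy30 over shScramble) of genes named in the text, from the authors' deposited table; bars are 1 standard error, and red marks an adjusted p under 0.05. Spon2 and Pcsk6 lie above 2, Dpy30 lies at -1.98, and the core subunits Wdr5, Ash2l and Rbbp5 lie near 0.

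Markers of the pancreatic lineages were mostly lower with shDpy30 in the authors' comparison, by small amounts. The 38 genes of hormones and secretory granules had a median log2 fold change of -0.30 with 29 below 0, and 0 of 10000 random lists of like abundance were as low. Within this list the authors' deposited table gave Ppy, the pancreatic polypeptide gene, at -1.14 ± 0.52 and Gast, the gastrin gene, at -1.20 ± 0.74. The major islet hormone genes lay on both sides of 0 in the authors' deposited table, with Gcg (glucagon) at -0.43 ± 0.64, Ins2 (insulin) at -0.19 ± 0.64, Ins1 at 0.19 ± 0.63, Sst (somatostatin) at 0.13 ± 0.71 and Ghrl (ghrelin) at 0.71 ± 0.64. Ins1 and Ins2 are near-identical, so the share of reads given to each is uncertain. Among 24 endocrine progenitor factors the median was -0.24 (200 of 10000 random lists as low), with Rfx3 at -1.44 ± 0.52, Rfx6 at -1.07 ± 0.47, St18 at -0.86 ± 0.47 and Neurog3, the master regulator of endocrine fate, at -0.59 ± 0.64 in the authors' deposited table. With a trend in transcript length and GC content subtracted, these genes were at -0.82, -1.03, -0.59 and -0.72, and the list median was -0.30. Neural and glial markers, many of which belong to secretory cells too, were lower alongside, with a median of -0.51. Without Rfx3 the endocrine progenitor median was -0.23, and this list lay inside the central 95% of random lists then and by its mean (-0.32). The 25 pancreas progenitor factors had a median of -0.17, inside that range, with Onecut2 at -1.56 ± 0.77, Hnf4g at -1.61 ± 1.09 and Gata6 at 0.64 ± 0.47 in the authors' deposited table. The progenitor genes Pdx1 (-0.24 ± 0.58), Sox9 (-0.24 ± 0.52) and Nkx6-1 (-0.20 ± 0.58) were within 1 SE of 0 in the authors' deposited table.

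Of 34 acinar genes, which encode digestive enzymes and their regulators, 28 lay below 0, with a median of -0.57 that 1 of 10000 random lists reached. Their standard errors were unusually wide: Cpa1 was at -0.41 ± 1.96, Prss2 at -2.12 ± 1.75 and Ctrb1 at -0.10 ± 2.09 in the authors' deposited table. The median error of the list was 1.64 times that of genes of like level. Random lists were matched on level and not on standard error. The place of the acinar median among them may therefore look more extreme than it is. Ptf1a, a regulator of progenitors and of acinar fate that was listed with the progenitor factors, was at -0.17 ± 4.12 in the authors' deposited table. Many of these genes sit in families of similar copies, so the share of reads given to each copy is uncertain. The 29 ductal genes had a median of -0.18 (98 of 10000 random lists as low), with 20 below 0. Krt19, a cytokeratin of duct cells, was at 0.34 ± 0.42 and Tspan8 at 0.98 ± 0.44 in the authors' deposited table. The ductal list was inside the central 95% of random lists when these were not matched on abundance, with no floor (-0.14) and by its mean (-0.12). No gene of these 5 lists passed over all genes or when adjusted over the list alone.

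Among the 3 signalling lists, the retinoic acid list alone had a median outside the central 95% of random lists. Its 15 retinoic acid responsive genes had a median of 0.40, above 9996 of 10000 random lists, with 12 above 0. In the authors' deposited table Cyp26b1, which degrades retinoic acid, was at 1.29 ± 0.75, Rarb, a receptor gene induced by retinoic acid, at 0.79 ± 0.47 and Aldh1a3 at -0.82 ± 0.70. The Notch pathway list (25 genes) had a median of -0.13, with 1723 of 10000 random lists at or below it, and its members were spread widely. In the authors' deposited table the Notch effector gene Hey2 was at 2.85 ± 0.77 and passed when adjusted over the list alone, Hey1 was at 1.31 ± 0.75, Lfng at 1.14 ± 0.60 and Mfng at -1.82 ± 0.81. The 14 Wnt target genes had a median of 0.19, with 9565 of 10000 random lists at or below it. Here Nkd1 was at 1.18 ± 0.50, Apcdd1 at 1.03 ± 0.49, Ccnd1 (cyclin D1) at -1.08 ± 0.46 and Tcf7 at -1.03 ± 0.61 in the authors' deposited table. No retinoic acid or Wnt target gene passed, over all genes or when adjusted over the list alone.

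Cell cycle genes were slightly higher with shDpy30. The 30 S phase genes had a median of 0.22 (23 above 0, above 9966 of 10000 random lists) and the 32 mitosis genes a median of 0.16 (26 above 0, above 9840 of 10000). The mean of the mitosis list was 0.085, inside the central 95% of random lists. In the authors' deposited table the replication licensing gene Cdt1 was at 0.87 ± 0.49, E2f2 at 0.91 ± 0.57 and Ube2c at 0.82 ± 0.51. Some members with long transcripts went the other way in the authors' deposited table, with Cenpf at -1.79 ± 0.64, Cenpe at -0.84 ± 0.56 and Mki67 at -0.67 ± 0.54. The 29 cell cycle inhibitors and p53 targets had a median of 0.11, inside the central 95% of random lists, and Cdkn1a (p21) was at -0.07 ± 0.43 in the authors' deposited table. The 28 replication-dependent histone genes, many of them near-identical, had a median of 0.12, which was 0.40 at a floor of 100, 0.21 with no floor and -0.10 once a trend with transcript length and GC content was subtracted. No gene of these lists passed over all genes or when adjusted over the list alone.

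Genes of glycolysis and the hypoxia response were lower as a group: 22 of 24 lay below 0, with a median of -0.42 that 0 of 10000 random lists reached. The lactate exporter gene Slc16a3 was at -1.78 ± 0.65, the phosphofructokinase gene Pfkl at -1.44 ± 0.55, hexokinase 2 (Hk2) at -1.36 ± 0.50 and carbonic anhydrase 9 (Car9), a hypoxia marker, at -1.29 ± 0.65 in the authors' deposited table. None of the 24 passed over all genes or when adjusted over the list alone. The 75 nuclear genes of oxidative phosphorylation had a median of 0.17 with 56 above 0, above 10000 of 10000 random lists. Their largest difference in the authors' deposited table was nevertheless a lower level, Cox6b2 at -1.94 ± 0.71. With the trend in transcript length and GC content subtracted the median was 0.07, inside the central 95% of random lists. The 81 cytosolic ribosomal protein genes had a median of 0.09 (above 9997 of 10000 random lists) and 0.047 with that trend subtracted, from Rps27 at -2.59 ± 1.93 to Rps29 at 0.88 ± 0.54 in the authors' deposited table. The 26 cholesterol and lipid synthesis genes had a median of -0.13, inside the central 95% of random lists, led by Idi1 at -0.92 ± 0.60 and Hmgcs1 at -0.79 ± 0.54 in the authors' deposited table. In these last lists, likewise, no gene passed over all genes or when adjusted over the list alone. The table holds 0 mitochondrially encoded genes.

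Interferon-stimulated genes, which are switched on by type I interferon and antiviral sensing, were lower in 36 of 38 cases. Their median was -0.85, and 0 of 10000 random lists of like abundance were as low. The authors' deposited table gave Ifi44 at -3.34 ± 1.00, Ifit3 at -2.28 ± 0.69, Rtp4 at -2.12 ± 0.72 and Oas1a at -1.79 ± 0.74. Irf7, a transcription factor gene of the pathway, was at -1.66 ± 0.65 in the authors' deposited table. Over all genes 0 of the 38 passed, and adjusted over the list alone 3 did, namely Ifi44, Ifit3 and Rtp4. Leukocyte markers, were higher in the same comparison, with a median of 0.76. Ifit3 shares sequence with Ifit3b, so their separate levels are uncertain. The 28 genes of the unfolded protein response had a median of -0.13, inside the central 95% of random lists, with the oxidase gene Ero1l at -0.96 ± 0.49 and Atf3 at -0.55 ± 0.48 in the authors' deposited table. The 28 immediate early and dissociation stress genes had a median of 0.15 (above 9755 of 10000), led by the heat shock genes Hspa1a (1.61 ± 0.57) and Hspa1b (1.61 ± 0.62), near-identical copies, and Klf2 (1.20 ± 0.56) in the authors' deposited table. That median was 0.06, inside the range of random lists, once the length and GC trend was subtracted. No gene of the last pair of lists passed over all genes or when adjusted over the list alone.

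Markers of other cell types also differed between the groups. Leukocyte markers were higher, with a median of 0.76, 18 of 20 above 0, and 10000 of 10000 random lists below. The macrophage genes C1qc (1.99 ± 0.81), Cx3cr1 (1.78 ± 0.81), Tyrobp (1.47 ± 0.58) and C1qb (1.40 ± 0.69) led the list in the authors' deposited table. Erythroid markers were lower in 8 of 8 cases with a median of -5.34, and with no floor the 13 members in the table had a median of -2.48. The globin genes had very wide errors in the authors' deposited table, such as Hbb-y at -5.71 ± 2.53 and Hbb-bs at -7.87 ± 4.62. Some globin genes are close copies of each other, which makes the separate levels of those copies uncertain. Whether this bears on the wide errors was not tested. Of 19 neural and glial markers 16 lay below 0 (median -0.51, 31 of 10000 random lists as low), with Elavl4 at -1.32 ± 0.68 and Nefl at -1.08 ± 0.54 in the authors' deposited table. No gene of these 3 lists passed over all genes or when adjusted over the list alone.

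Endothelial markers had a median of -0.54 over 14 genes, of which 10 lay below 0 and 4 above. In the authors' deposited table Sox17 was at 2.16 ± 0.72, Kdr (VEGF receptor) at 1.73 ± 0.51, Egfl7 at -1.44 ± 0.50 and Pecam1 at -1.97 ± 1.16. Sox17, Kdr, Egfl7 and Cdh5 passed when adjusted over the list alone and 0 passed over all genes. Cdh5, a lower gene, has a fitted value too extreme to give as a fold. The endothelial median depended on the floor: it was -0.15 at a mean normalized count of at least 100, inside the range of random lists, and -0.98 with no floor, while the mean was -1.03. That mean includes Cdh5, set to the limit of 10 below 0 used for means, and the mean without Cdh5 was not computed. Mesenchymal genes ranged widely in level in the authors' deposited table, from a mean normalized count of 37.6 for Mfap5 to 105352 for Fn1 and 123448 for Col3a1. Their list of 35 genes had a median of 0.08, inside the central 95% of random lists. Single mesenchymal genes differed more in the authors' deposited table, with Lum at -1.61 ± 0.50, Thy1 at -1.33 ± 0.58, Mfap5 at 3.07 ± 1.07 and Upk3b at 1.41 ± 0.94, of which Lum and no other passed when adjusted over the list alone. Among genes of neighbouring organs, the 19 stomach and intestine genes had a median of 0.23 and the 11 liver genes a median of 0.39, both above the central 95% of random lists. The stomach and intestine list was inside that range by its mean (0.15), at a floor of 100 (0.14) and without its largest member (0.13). Members of both lists were spread widely in the authors' deposited table, from Apob at -3.90 ± 2.02 to Gkn2 at 2.92 ± 1.74. The mean of the liver list was -0.19, opposite in sign to its median, and with no floor its median was 0.11, inside the range. Neither of these lists had a gene that passed over all genes or when adjusted over the list alone.

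**Figure D2:**
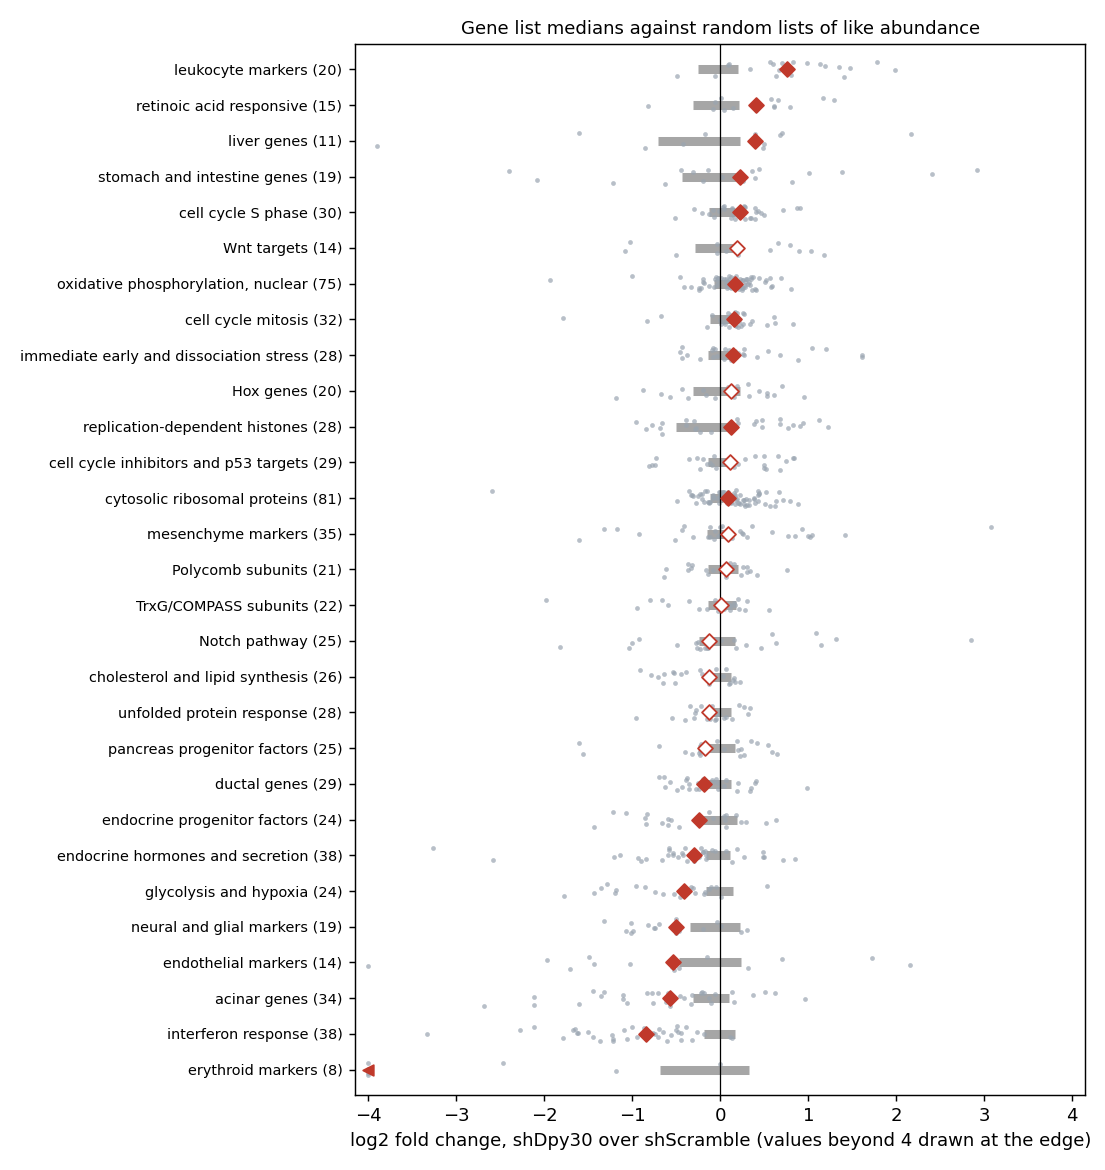
Log2 fold change (x axis, shDpy30 over shScramble) of 29 gene lists, with the number of members in brackets. Dots are member genes, diamonds are list medians (filled where outside the central 95% of 10000 random lists of like abundance, drawn as a thick bar), and values beyond 4 are drawn at the edge, including the erythroid median of -5.34.

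Of the 29 lists with at least 5 measured members, 9 had a median below the central 95% of random lists and 10 a median above it, against 1.45 expected for random lists. Genes within a list are regulated together, while the random lists hold unrelated genes. This count therefore describes the authors' comparison and is not a test of the conditions. Subtracting a trend in transcript length and GC content gave 11 lists below and 8 above.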

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

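Alternatives chosen after the data were seen were the unadjusted p, adjustment over genes at a mean normalized count of at least 100, statistics divided by their robust spread, and subtraction of the length and GC trend. The others were fixed before. The count of 2 genes higher and 0 lower held with an added 2-fold limit, a floor of 100, adjustment over all rows and adjustment over genes at 100 or more. The 2-fold limit and the floor could not change it. Spon2 and Pcsk6 lie at log2 fold changes of 2.12 and 2.13 and mean normalized counts of 1392 and 2317. Adjustment over all rows could not either, since the deposited adjustment is that one. It was 0 higher at an adjusted p under 0.01, 182 higher and 322 lower at an unadjusted p under 0.05, and 43 higher and 72 lower with statistics divided by their robust spread. Dpy30 was among those 72, with an adjusted p of 1.61e-05, which the scaling lowers by construction, against 0.138 in the authors' deposited table. It did not pass with adjustment over all rows or over genes at 100 or more. At least 2-fold with no p, 373 were higher and 875 lower at a floor of 20, 671 and 1904 with no floor, and 222 and 451 at a floor of 100. These counts differ by the construction of each rule. Dpy30 was at -1.99 relative to the median of genes at 100 or more and at -1.87 minus the length and GC trend.

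List medians kept their side of the random range, and those outside it kept their sign, except as follows; the cause was not tested. With the mean in place of the median, TrxG subunits (-0.16) changed sign and left the range below. That mean includes the targeted gene Dpy30 at -1.98. By the mean too, liver genes (-0.19) changed sign, and mesenchyme (0.15) and cholesterol genes (-0.24) left the range. Endocrine progenitor factors (-0.32), ductal genes (-0.12), mitosis (0.085) and stomach and intestine genes (0.15) fell inside it. With random lists not matched on level, ductal genes (-0.18), immediate early genes (0.15) and histones (0.12) were inside. With no floor, ductal (-0.14) and liver genes (0.11) were inside and Wnt targets (0.21) outside. At a floor of 100, endothelial (-0.15, against -0.98 with no floor and -1.03 by the mean) and stomach and intestine genes (0.14) were inside, and the erythroid and liver lists had too few members. The endothelial mean includes Cdh5, set to the limit of 10 below 0 used for means. Without the member with the largest change, endocrine progenitor factors (-0.23), immediate early genes (0.12), stomach and intestine genes (0.13) and histones (0.057) were inside. Minus the length and GC trend, histones changed sign (-0.10), immediate early (0.060) and oxidative phosphorylation genes (0.070) were inside, and Wnt targets (0.21), unfolded protein response (-0.13) and cholesterol genes (-0.16) outside. Centring on genes at 100 or more moves every list and random list alike, so it tests nothing about their order. Medians inside the range lie near 0 and some crossed it while staying inside: pancreas progenitor factors at a floor of 100 (0.002), Notch genes by the mean (0.07) and at a floor of 100 (0.002), Hox genes with no floor (-0.03) and minus the trend (-0.02), and TrxG subunits when centred (-0.004) and minus the trend (-0.06). Pseudocounts and other scalings need values per library and were not run. Other fold limits do not need them but were not run either. No paired analysis was possible because each group had 1 library. Depth per library is unknown, and it limits the low genes most.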

Other observations

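Gene groups outside the fixed lists were chosen after the values had been seen, so their places among random lists are not independent evidence. Wnt ligand genes were higher in 12 of 13 cases, with a median of 0.89 above 10000 of 10000 random lists. The authors' deposited table gave Wnt2 at 2.27 ± 0.85, Wnt6 at 2.26 ± 0.63, Wnt11 at 1.78 ± 0.65 and Wnt4 at 1.38 ± 0.44. Without Wnt4, Wnt6 and Wnt11, which drew attention to the family, the other 10 had a median of 0.82, again above 10000 of 10000. Elastic fibre genes had a median of 0.34 over 16 members, 11 above 0 and 5 below, and of 0.22 without the largest member. Among those above 0 were Mfap5 at 3.07 ± 1.07, Fbln5 at 1.61 ± 0.43 and Loxl1 at 1.49 ± 0.51 in the authors' deposited table. Smooth muscle genes had a median of 0.32 over 12 members, with Acta2 at 0.77 ± 0.46 and Myh11 at -1.41 ± 0.46 in the authors' deposited table. With the trend in transcript length and GC content subtracted, the medians of the full Wnt ligand, elastic fibre and smooth muscle lists were 0.63, 0.18 and 0.15.

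Primary cilium genes were lower in 31 of 41 cases, with a median of -0.19 that 8 of 10000 random lists reached. Nuclear long non-coding RNAs had a median of -0.36 over 10 members, of which 6 lay below 0 and 4 above, and the authors' deposited table gave Malat1 at -1.80 ± 0.59, Kcnq1ot1 at -1.65 ± 0.61 and Xist at -1.71 ± 0.65. The Y-linked genes Ddx3y (-0.97 ± 0.58), Uty (-0.60 ± 0.56), Eif2s3y (-0.18 ± 0.45) and Kdm5d (-0.15 ± 0.45) were not higher in the authors' deposited table, so Xist and these genes did not move in opposite directions. MHC class I genes had a median of -0.34 and imprinted genes a median of 0.01. The snoRNA genes had a median of 0.08 and the microRNA genes a median of -0.09.

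Of the tests below, those of leukocytes, of the lentiviral preparations, of a fit to 2 libraries and of abundant acinar genes were chosen after the values had been seen. The others were fixed before their result was seen.

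Interferon-stimulated genes were lower, with a list median of -0.85. Loss of leukocytes, which respond strongly to interferon, would lower their markers as well, but the leukocyte list had a median of 0.76. A trend in transcript length and GC content does not account for it either, since the median after that trend was subtracted was -0.80. A candidate explanation that stays open is a difference between the lentiviral preparations in dose or in what they trigger. With 1 library per construct described, and the libraries of the fit not given, it cannot be separated from Dpy30 loss. A lower interferon response after loss of Dpy30 is the biological hypothesis and is equally untested.

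Long transcripts were lower and short ones higher, with a difference of -0.23 ± 0.02 (bootstrap SE over genes) between the medians of the longest and shortest decile. Low read counts do not explain it, since it was -0.27 ± 0.02 at a mean normalized count of at least 1000. After the trend with the genomic span of the gene was removed the difference was -0.062 ± 0.020, so gene span is a candidate explanation, through transcription of long genes or features that go with span. In reverse, the difference between the widest and narrowest span decile went from -0.27 ± 0.02 to -0.13 ± 0.02 after the length trend was removed. Length thus carries part of the span trend too. Between the highest and lowest GC decile the difference was larger, 0.53 ± 0.02, and span was not adjusted for GC content. GC content as the whole cause is argued against, though not strongly: -0.13 was left after its trend was removed, beyond the bound of -0.12 set beforehand by 0.018 ± 0.0096 (paired bootstrap SE), and it may still carry part. Across genes, which are not independent replicates, GC content had the stronger relation, with a Spearman rho of 0.31 against -0.13 for length; library chemistry and RNA quality were not tested.

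Acinar genes had wide standard errors for their abundance, with a median of 1.64 times that of genes of like level. A fit to only the 2 libraries cannot give a wide error to an abundant gene with a small change, since its spread would follow their difference, yet 10 such genes were found, among them Ctrb1, Clps, Gpx2, Mmp9 and Cd36. The authors' fit may therefore have held further libraries that differ in these genes. Reads shared between near-identical copies do not explain the 5 abundant members outside tandem families, whose lowest relative error was 4.00. Over all acinar genes outside tandem families the median was 1.51 ± 0.79 (bootstrap SE), which leaves the rest open. Varying acinar differentiation between libraries stays open too, with 1.16 ± 0.66 (bootstrap SE) for 4 acinar transcription factor genes.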
